A study of Mus musculus with 9 samples.

How the data were processed

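Total RNA of mouse morulae made by in vitro fertilization was sequenced in 9 libraries, 3 for each sire treatment. Each deposited file held raw counts per gene for 1 library, made by the authors with featureCounts against the genome build GRCm39, per the submitters' processing notes. Those notes also name DESeq2. In 4 files the column header names RNA STAR as the source of the alignments, per the file headers, and in the other 5 files the aligner is not given in the sources used here. Versions, the gene annotation and the strand setting are likewise not given. Genes that share reads with pseudogenes or near-identical copies, such as ribosomal protein genes, Gapdh, Eno1 and Uba1y, and genes that overlap or lie antisense to others, therefore carry uncertain counts.

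All files listed the same 53819 rows, of which 1442 carried an Ensembl identifier and no symbol, and no row was a total or an unassigned class. Library totals ran from 6263465 to 27619281 counts. The mitochondrial ribosomal RNA gene mt-Rnr2 took 4.44 to 14.7 percent of the counts of a library. The ribosomal RNA gene Rn18s took 1.28 percent in control 1 and 1.92 percent in 10% ethanol 1, and at most 0.119 percent elsewhere. Each pair of libraries differed by more than sampling noise, with a chi-square per degree of freedom of at least 116 over genes with 10 or more counts in the pair. No gene coordinates are given, because the genome used here only for transcript length and base composition (GENCODE M21) is of another build.

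The main test was fixed before the data were examined. Genes were filtered with edgeR's filterByExpr by group, which left 12488, and libraries were scaled with TMM factors. A quasi-likelihood model with 3 groups was fitted to all 9 libraries so that the groups shared 1 estimate of the spread. Contrasts were 6% against control, 10% against control, 10% against 6%, and the mean of both ethanol groups against control. P-values were adjusted by the Benjamini-Hochberg method over all tested genes and compared with 0.05. Standard errors were taken from the log2 fold change and its F statistic. CPM of named genes, Eif2s3y and Uba1y among them, were on TMM-scaled library sizes. The CPM of Xist, Uty, Ddx3y and Usp9y and the sums over lists were on full library totals. A count of 0 over a group was read against a limit of 3 counts, which covers counting error only. The software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and sva 3.50.0.

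Of 32 gene lists fixed before the data were examined, 29 had at least 5 tested members and were tested with camera at a preset inter-gene correlation of 0.01, with the correlation estimated per list, and with fry. List p-values were adjusted over the lists tested in a comparison, which were 29 in the fit to all 9 libraries. Fits to fewer libraries were filtered anew and could test other lists. The long-header fit also tested the cumulus and granulosa list. The lists covered energy metabolism, ribosomes, stress responses, embryo lineages and stages, chromatin, growth and sex, and markers of cells from outside the embryo.

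Named genes followed a rule fixed in advance. Where fewer than 10 genes passed, as in every comparison, the rule took the 5 higher and 5 lower genes of smallest p at 10 CPM or more in a group, leaving out predicted symbols. It added the 2 smallest-p members of the oxidative phosphorylation, ribosomal, pluripotency, trophectoderm, maternal oocyte and p53 lists, where ribosomal was taken as cytosolic ribosomal. For the comparisons with control it also added the 2 smallest-p members of each list that passed, and Xist and the Y-linked genes were always read. Not every gene that the rule took is described singly, and 1 result was left out and is not reported here.

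The tests were tried on simulated counts drawn from the real means, dispersions and library sizes, with 50 genes changed at each of 4 sizes. For 6% against control, with 11974 genes in the simulated step, edgeR recovered 0 of 50 genes changed 4-fold, 14 of 50 changed 16-fold, 30 of 50 changed 64-fold and 39 of 50 changed 256-fold, with 0 false calls among 83. DESeq2 made 183 calls there, of which 69 were false. For 10% against control, with 11943 genes, edgeR recovered 1, 18, 36 and 36 of 50 at the same folds, with 4 false calls among 95, and 82 of 212 DESeq2 calls were false. The simulated dispersions were edgeR's own, which favours edgeR in that comparison of tools.

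Alternatives set in advance were RLE scaling, library size alone, a looser and a stricter filter, DESeq2, limma voom with quality weights, only the groups compared, a robust fit, 1 surrogate variable, mitochondrially encoded genes left out, a threshold of 0.1, and each library left out in turn. Header form as a term, each header form alone, rRNA-like genes left out and thinning to the smallest library were added after the data were seen. Replicate numbers were given in accession order and pair nothing. Other assignments of the libraries to groups were refitted, 10 for each pair of groups and 100 for both ethanol groups against control, the real assignment counted among them each time.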

Results

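RNA from mouse embryos at the morula stage, the stage at which the blastomeres compact into a ball before the blastocyst cavity forms, was sequenced to ask whether alcohol drunk by the father before conception was followed by altered gene expression in embryos made by in vitro fertilization. The embryos were of the C57BL/6J strain and fell into 3 groups by the treatment of the sire, namely control, 6% ethanol and 10% ethanol, with 3 libraries in each. Gene counts per library summed to between 6263465 and 27619281. Nothing in the labels says how many embryos or how many sires stand behind a library. The p-values of single genes therefore rest on the spread between these libraries, which may be technical in part. The set test at the preset correlation compares the genes of a list with the other genes, and treats them as nearly independent. A small p from it is thus no measure of how far libraries of a group vary. Values per gene are CPM, the usual depth-normalised counts, on scaled library sizes, given as mean ± SD with n = 3 unless single libraries are named.

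Libraries of one group were about as alike as libraries of different groups. The correlation of log2 CPM across genes, which are not independent replicates, had a median of 0.787 over the 9 pairs of libraries from one group and 0.788 over the 27 pairs from different groups. The count column carried a long header naming the aligner in 4 files (control 2, 6% ethanol 1, 10% ethanol 1 and 10% ethanol 2) and a short header in 5. The 6 pairs among the long-header libraries correlated at 0.875 to 0.891, and the 10 pairs among the short-header libraries at 0.713 to 0.805. Long-header libraries held 19574710 to 27619281 counts and short-header libraries 6263465 to 11026334. When each library was thinned to 6263465 counts the medians were still 0.888 and 0.780. Values with header form as a term, or within it, are therefore given for many results, though not for each one it moved. What the header form stands for is left open. The common biological coefficient of variation was 0.911, and the median standard error of a log2 fold change was 1.02 for 6% ethanol and 1.01 for 10% ethanol against control.

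**Figure D1:**
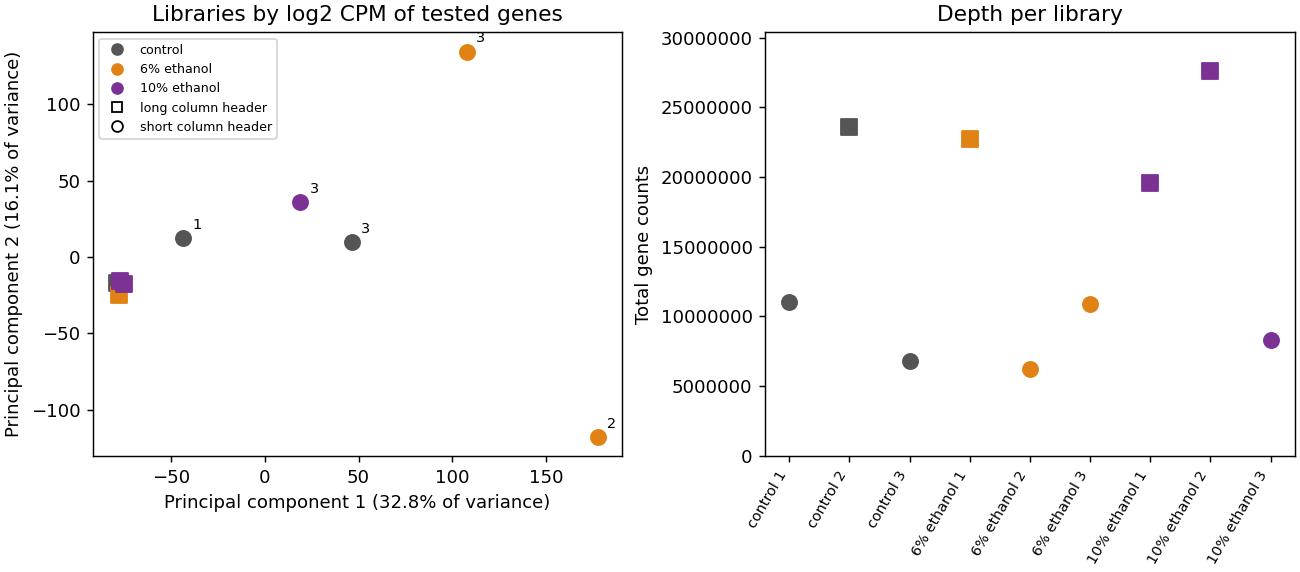
Left, the first and second principal components of log2 CPM over the 12488 tested genes, with the percent of variance on each axis; colour marks the sire group, squares the 4 long-header libraries and circles the 5 short-header ones, whose replicate numbers are written beside them. Right, total gene counts per library. The 4 squares, from all 3 groups, lie together between -78.6 and -74.6 on the first component, and the 5 circles spread from -43.2 to 177.6.

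In morulae of sires given 6% ethanol, most genes of the unfolded protein, glycolysis and antioxidant lists had lower counts than in controls. The mitochondrially encoded messenger RNAs had higher ones. By edgeR no member of these lists passed over all genes. Of the antioxidant list, 23 of 32 members lay below 0. It passed the set test at a preset correlation (adjusted p = 0.0101) and not at an estimated one (0.362). Of the unfolded protein and integrated stress response list, 28 of 32 tested members lay below 0, with a median log2 fold change of -0.96, which was -0.42 without control 1 and -1.49 without 6% ethanol 1. The set test passed this list at a preset inter-gene correlation (adjusted p = 2.58e-05, or 0.0441 without control 1) and not at an estimated one (0.553). Herpud1, which acts in the disposal of misfolded endoplasmic reticulum proteins, had 56.1 ± 45.8 CPM in controls and 1.58 ± 0.737 with 6% ethanol. Hsp90b1, the endoplasmic reticulum chaperone GRP94, had 191 ± 151 and 39.0 ± 5.62 CPM. The lowest control library, at 87.7 CPM, lay above all 3 libraries of the 6% group. In glycolysis, 16 of 17 members lay below 0 with a median of -1.27, or -0.73 without control 2. That list passed at the preset correlation (adjusted p = 8.18e-05, or 0.0133 without control 2) and not at an estimated one (0.489). Its member Aldoa, a fructose-bisphosphate aldolase, had 159 ± 35.9 and 58.5 ± 40.4 CPM.

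All 13 mitochondrially encoded genes were above 0 in that comparison, with a median of 1.57, which was 2.43 without control 3 and 1.05 without 6% ethanol 3. The list passed at the preset correlation (adjusted p = 2.86e-06, or 0.00879 without 6% ethanol 3) and not at an estimated one (0.553). That estimate was 0.765, so the 13 genes are not separate observations. mt-Nd5, a subunit of respiratory complex I, had 1076 ± 738 CPM in controls and 3201 ± 2154 with 6% ethanol. The short-header libraries 6% ethanol 2 and 3 carried the high values, 3057 and 5424 CPM, against 1122.5 CPM in the long-header library 6% ethanol 1. Those high libraries also had the largest shares of tested genes at 0 counts, 13.5 and 8.42 percent, and the lowest TMM factors, 0.840 and 0.836. Of the nuclear encoded oxidative phosphorylation genes 34 of 78 were above 0, and that list did not pass (median -0.06, adjusted p = 0.721). Ndufa8, an accessory subunit of complex I, nevertheless had 57.7 ± 13.5 CPM in controls and 19.7 ± 2.88 with 6% ethanol, without overlap (log2 fold change -1.55 ± 0.54 SE, adjusted p = 0.799). Uqcr11, a small subunit of complex III, had 13.5 ± 3.55 and 1.68 ± 1.01 CPM, and passed by DESeq2 (adjusted p = 0.0288) and not by edgeR (0.799).

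edgeR called no single gene at 6% ethanol. Its quasi-likelihood test with Benjamini-Hochberg adjustment passed 0 of 12488 genes, with a smallest adjusted p of 0.799. At an unadjusted p under 0.05 there were 779 genes, 399 higher and 380 lower, where 624.4 would fall by chance. Without 6% ethanol 1, the only long-header library of its group, there were 2068 of 13631 tested. DESeq2 called 53 and limma voom with quality weights 0. Among the genes of smallest p was Gpx4, the phospholipid hydroperoxide glutathione peroxidase that guards against ferroptosis, with 1499.8 ± 1174 CPM in controls and 198 ± 105 with 6% ethanol (log2 fold change -2.92 ± 0.67 SE). Dbr1, the debranching enzyme of intron lariats, had 16.7 ± 8.39 and 236 ± 229 CPM (3.83 ± 0.78). Higher means were also measured for Lonp1, a protease of the mitochondrial matrix, with 102 ± 35.8 and 556 ± 476 CPM, and for Mrpl1, a mitochondrial ribosomal protein, with 45.5 ± 15.5 and 402 ± 481 CPM. Efhd2 (-3.22 ± 0.77) and Vasp (-2.91 ± 0.73), both actin-binding proteins, were lower. For each of these the adjusted p by edgeR was 0.799, and DESeq2 called Dbr1 (adjusted p = 0.00435) and Efhd2 (0.0283) of them.

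Some of the large differences came from a single library. Stk4, a kinase of the Hippo pathway, reached 28333 CPM in 6% ethanol 3, against 35.1 and 232 CPM in the other libraries of that group and 72.2 to 116 CPM in controls. Mthfsd stood at 519 CPM in control 3 and at 8.002 and 27.64 CPM in the other controls, while the 6% libraries held 1.87 to 3.82 CPM (adjusted p = 0.00149 by DESeq2 and 0.799 by edgeR). Kmt2a, a histone H3 lysine 4 methyltransferase, had 167 CPM in control 1, 5.64 and 1.61 CPM in the other controls, and at most 0.0847 CPM in the 6% group. Junb had 0 counts in all 3 libraries of the 6% group and 3.10 ± 4.27 CPM in controls, at least 39.2-fold more when 3 counts over the whole group are taken as the limit.

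The set test (camera, preset inter-gene correlation 0.01) passed 6 of 29 lists at 6% ethanol. The mitochondrially encoded list rose (adjusted p = 2.86e-06), as did the Y-linked list (adjusted p = 0.0182). Unfolded protein and integrated stress response (adjusted p = 2.58e-05), glycolysis (8.18e-05), immediate early and handling stress (0.00638) and antioxidant and NRF2 targets (0.0101) fell. With an estimated correlation 0 of the 6 held, at adjusted p = 0.362 for the Y-linked and antioxidant lists, 0.489 for glycolysis and 0.553 for the other 3. By edgeR no member of these lists passed over all genes, and DESeq2 called Herpud1 (adjusted p = 0.0137), Uba1y (0.00110) and Junb (0.0298). Adjusted over the list alone, 2 members of the unfolded protein list, 1 of the antioxidant list and 1 of the Y-linked list passed. The immediate early call ended without control 1 (adjusted p = 0.106) or control 2 (0.0681), and the Y-linked call without control 1 (0.0827) or control 2 (0.0713). Their medians, -1.25 and 1.87, were -2.06 without 6% ethanol 1 and 1.11 (adjusted p = 0.0346) without 6% ethanol 2.

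Within header form, the single long-header library of the 6% group lay above the single long-header control by a median of only 0.33 over the mitochondrially encoded list. The short-header libraries gave 1.79 (adjusted p = 8.19e-07). For glycolysis the medians were -0.95, from the single pair of long-header libraries, and -1.02 (adjusted p = 0.0154) in short-header libraries. The control of that pair, control 2, had the highest glycolysis sum of the 3 controls. The unfolded protein list had medians of -0.59 in the pair and -1.47 (adjusted p = 0.00377) in short-header libraries. The immediate early list had -1.03 in the pair and -2.22 (0.0426) in short-header libraries. The antioxidant list had medians of -0.44 in the pair and -0.39 (0.182) in short-header libraries, and the Y-linked list 0.96 and 2.03 (0.182). Neither passed in short-header libraries. For the pair only medians are given, because with 1 library each neither group compared had a spread of its own. The spread in the long-header fit came only from libraries of the higher dose, which are not in this comparison. In fits within header form a group with 1 library is assumed to vary like the others.

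**Figure D2:**
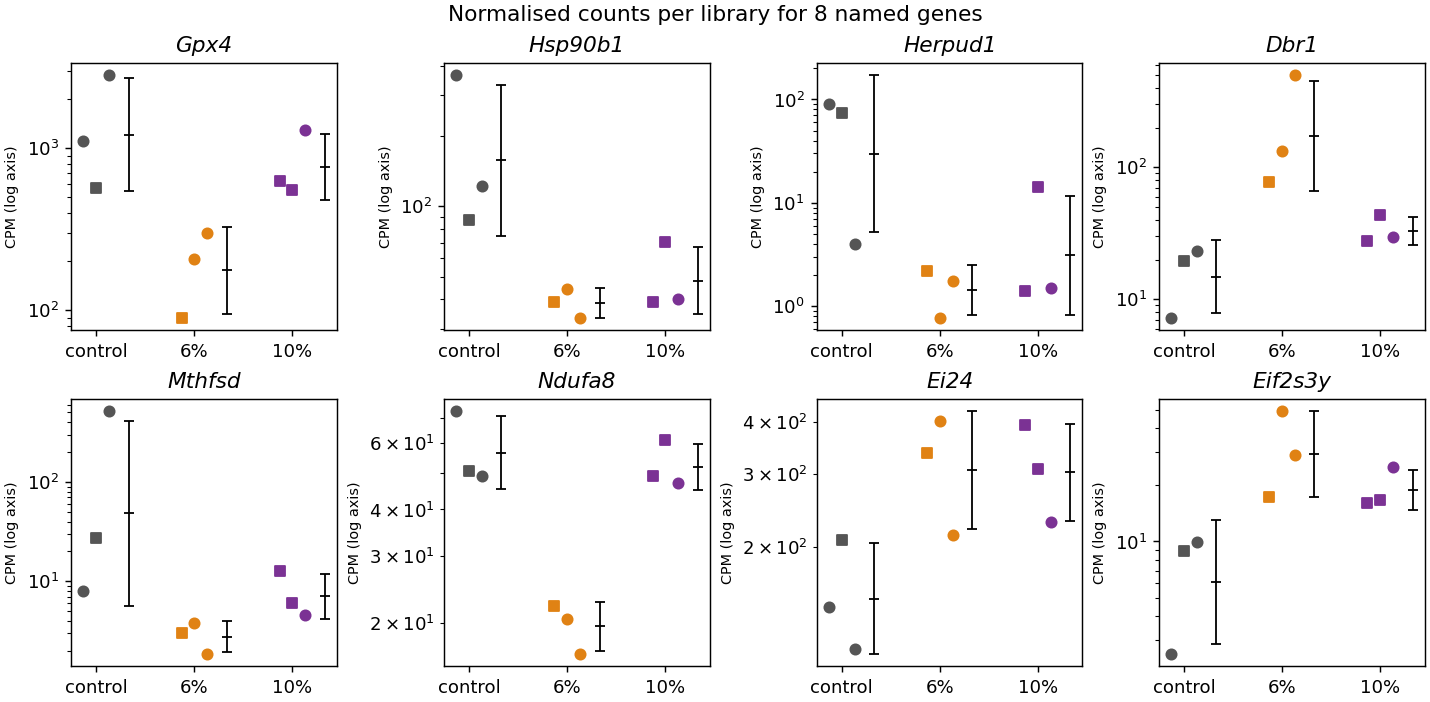
Normalised counts (CPM, log axis) per library of 8 named genes in control, 6% and 10% ethanol groups. Squares are long-header and circles short-header libraries, and the bar beside each group is the mean ± SD of log2 CPM (n = 3). Hsp90b1 lies below 87.7 CPM, the lowest control, in all 6 ethanol libraries, whereas Gpx4 and Ndufa8 lie apart from controls at 6% ethanol and overlap with them at 10%.

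At 10% ethanol most genes of the unfolded protein and glycolysis lists had lower counts than in the controls, which are the ones used for 6% ethanol. Most genes of the cytosolic ribosome and of nuclear encoded oxidative phosphorylation lay slightly lower. These 4 lists passed at the preset correlation and not at an estimated one (adjusted p = 0.900 for each). The unfolded protein median came near 0 without control 1, and that of glycolysis without control 2, and both calls then ended. Without control 3 the ribosomal median was 0.11 (adjusted p = 0.488) and that of oxidative phosphorylation -0.05 (0.927), and with header form as a term they were -0.10 (0.749) and -0.25 (0.216). Hsp90b1 had 191 ± 151 CPM in controls and 49.9 ± 17.6 with 10% ethanol (log2 fold change -1.94 ± 0.61 SE). Gapdh, the glyceraldehyde-3-phosphate dehydrogenase of glycolysis, had 159 ± 29.7 and 53.02 ± 40.6 CPM (-1.58 ± 0.85). Fgf4, the growth factor through which the inner cell mass signals to its neighbours, had 78.7 ± 16.99 CPM in controls and 10.2 ± 2.73 with 10% ethanol (-2.95 ± 0.93), without overlap. Ctsl, a lysosomal cathepsin, had 962 ± 149 and 1759 ± 212 CPM (0.87 ± 0.42), also without overlap. None of these genes passed by edgeR, each with an adjusted p of 0.9999.

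Lower at 10% ethanol, among the genes of smallest p or members of the named lists, were Fam221a (-3.60 ± 0.95), Brdt, a bromodomain protein best known from male germ cells (-3.69 ± 1.04), and Gsta4, a glutathione S-transferase (-4.14 ± 1.21). DESeq2 called Fam221a (adjusted p = 0.0225) and Brdt (0.00572) of these 3. Hmbox1, a homeobox protein that binds telomeres, had 16.9 ± 4.12 CPM in controls and 76.0 ± 29.4 with 10% ethanol (2.16 ± 0.67). Single libraries again made some of the means. Mavs, the mitochondrial adaptor of RNA sensing, reached 727 CPM in 10% ethanol 2 and 6.38 and 3.76 CPM in the other libraries of the group. Arl5c had 0 counts in all 3 controls and 188 CPM in 10% ethanol 3, with 1.67 and 0.0731 CPM in the other libraries of the group. D7Bwg0826e ranged from 0.880 to 46.8 CPM in controls and from 0 to 0.0523 CPM with 10% ethanol. DESeq2 called Arl5c (adjusted p = 0.000190) and D7Bwg0826e (5.36e-05), and edgeR did not.

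edgeR called 0 of 12488 genes for 10% ethanol against control, with 267 at an unadjusted p under 0.05, 107 higher and 160 lower, where chance gives 624.4. The 267 became 442, 497 and 459 without 6% ethanol 1, 2 and 3, and 452 without 10% ethanol 3. DESeq2 called 23 and limma voom 0. The set test passed 6 of 29 lists. The Y-linked list (median 2.04, adjusted p = 0.00135) and the autophagy, lysosome and mTORC1 list (0.29, 29 of 38 above 0, 0.0190) rose. Cytosolic ribosomal proteins (-0.33, 66 of 79 below 0, 0.00266), nuclear encoded oxidative phosphorylation (-0.34, 58 of 78 below 0, 0.0157), unfolded protein and integrated stress response (-0.59, 23 of 32 below 0, 0.0435) and glycolysis (-0.58, 13 of 17 below 0, 0.0435) fell. With an estimated correlation the adjusted p was 0.170 for the Y-linked list and 0.900 for the other 5.

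With header form as a term, the Y-linked (adjusted p = 0.000206), unfolded protein (0.00564) and glycolysis (0.00131) lists still passed, while the ribosomal, oxidative phosphorylation and autophagy (median 0.04, adjusted p = 0.187) lists did not. Within header form the glycolysis medians were -1.11 (adjusted p = 0.00147) in long-header and -0.25 (0.751) in short-header libraries. Those of the unfolded protein list were -0.20 (0.437) and -1.04 (0.00691). The autophagy medians were 0.23 in long-header and -0.08 in short-header libraries. In this comparison the long-header controls and the short-header 10% group are 1 library each, so values within header form may describe that library. Without control 3 the ribosomal, oxidative phosphorylation and autophagy (0.237) calls ended. Without 10% ethanol 2 these 3 calls ended as well (0.153 each), and the autophagy call also ended without 10% ethanol 1 (0.124). Without 10% ethanol 3 the medians of the ribosomal, oxidative phosphorylation and autophagy lists were -0.59, -0.60 and 0.45. The ribosomal median was -0.52 without control 1 and -0.53 without control 2, and the autophagy median was 0.57 without control 2. The unfolded protein call ended without control 1 (median -0.04, adjusted p = 0.970), control 2 (0.0824) or 10% ethanol 3 (0.178), and without control 3 its median was -0.97. The glycolysis call ended without control 2 (median -0.07, adjusted p = 0.611), 10% ethanol 1 (0.151) or 10% ethanol 3 (0.170). Of the 6 lists the Y-linked one passed without each of the 9 libraries in turn (largest adjusted p = 0.0390, median 0.62, without 10% ethanol 3), but within header form its medians were 0.70 (adjusted p = 0.375) in long-header and 1.99 (0.00691) in short-header libraries.

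**Figure D3:**
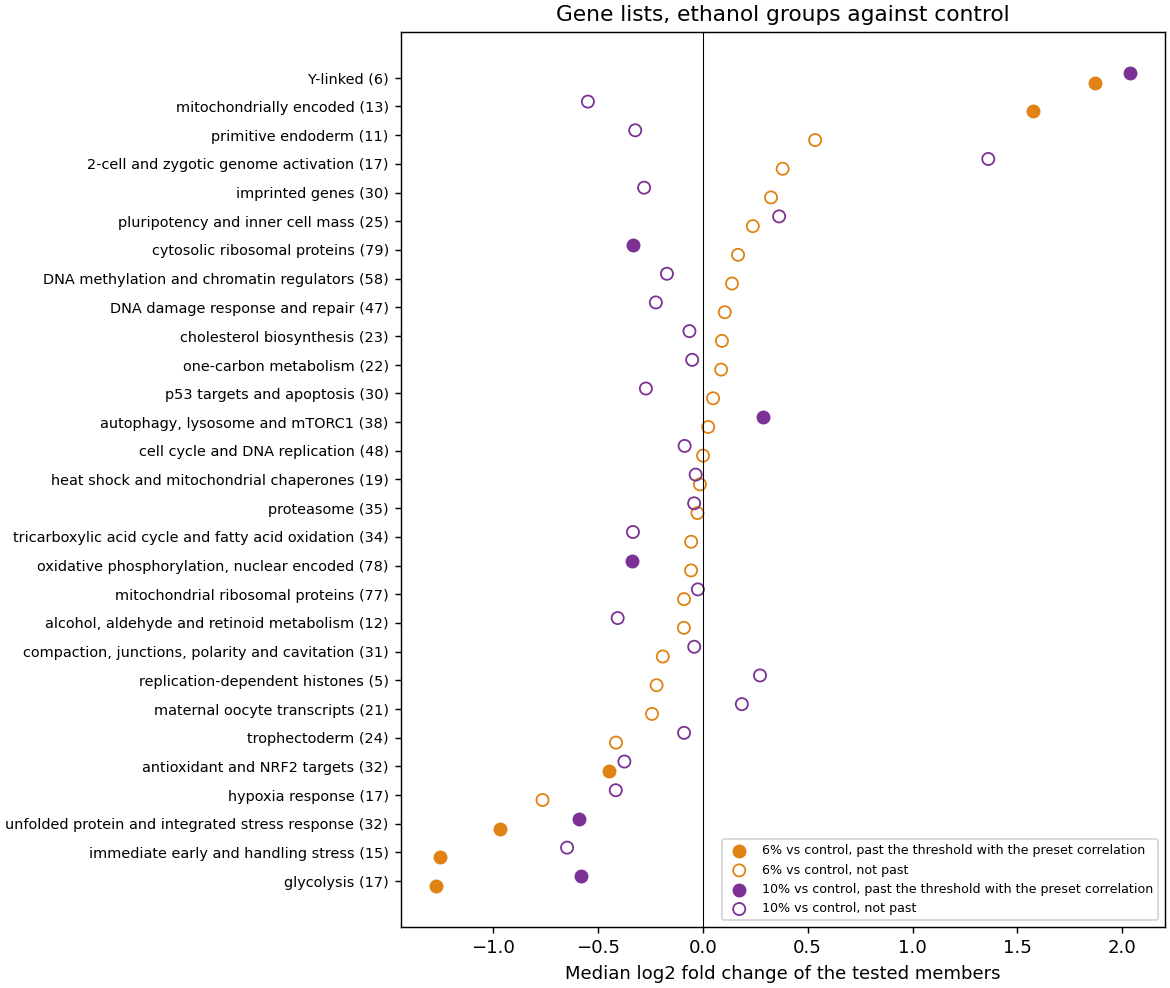
Median log2 fold change over the tested members of each of 29 gene lists fixed in advance, with the number of tested members in brackets, for 6% ethanol (orange) and 10% ethanol (purple) against control. Filled points passed the set test with a preset correlation of 0.01, and 0 lists passed with an estimated one. Glycolysis and the unfolded protein list lie left of 0 at both doses, and the mitochondrially encoded list lies at 1.57 for 6% and -0.55 for 10% ethanol.

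The difference between the doses was tested directly. The mitochondrially encoded messenger RNAs were lower at 10% than at 6% ethanol in 13 of 13 genes, with a median log2 fold change of -2.05. Their summed CPM was 26564 ± 18211 with 6% ethanol and 9235 ± 5537 with 10%. It was 7831 in 6% ethanol 1, 27660 in 6% ethanol 2 and 44202 in 6% ethanol 3. Cytosolic ribosomal protein genes were lower in 60 of 79, with a median of -0.63, or -0.06 (adjusted p = 0.612) without 6% ethanol 2. Ndufa8 stood at 52.4 ± 7.65 CPM at 10% and at 19.7 ± 2.88 at 6% ethanol (1.41 ± 0.54 SE), and Dbr1 stood at 33.7 ± 8.70 CPM against 236 ± 229 (-2.81 ± 0.74). Raly, an RNA-binding protein of the hnRNP family, had 58.0 ± 16.6 CPM at 6% and 243 ± 110 at 10% (2.06 ± 0.51). Bpnt1, a bisphosphate nucleotidase, had 222 ± 183 and 9.54 ± 1.55 CPM (-4.54 ± 1.11), and Mybl1, a transcription factor, 28.7 ± 19.8 and 1.70 ± 0.896 CPM (-4.06 ± 1.08). Nlrp5, a maternal effect gene of the oocyte, had 0.271 ± 0.29955 and 8.08 ± 6.32 CPM.

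By edgeR none of these genes passed (adjusted p = 0.806 for each), and DESeq2 called Bpnt1 (adjusted p = 0.0187), Mybl1 (0.00380) and Nlrp5 (0.0284). edgeR called 0 of 12488 genes between the doses, with 665 at an unadjusted p under 0.05, DESeq2 called 63 and limma voom 0. The 665 became 2208 without 6% ethanol 1, the only long-header library of its group. They became 442 without 10% ethanol 1 and 421 without 10% ethanol 2. The set test called 2 of 29 lists, both falling, the mitochondrially encoded (adjusted p = 2.73e-10, 0.959 with an estimated correlation) and the cytosolic ribosomal (1.47e-05, 0.961 with an estimated correlation). Adjusted over the list alone, 7 of the 13 mitochondrially encoded genes passed. Their estimated inter-gene correlation was 0.80, so the 13 genes are not separate observations and these counts add little to the list call. Between long-header libraries the medians were -0.31 and 0.02, and between short-header libraries -2.06 and -0.48. Only medians are given, because the long-header 6% group and the short-header 10% group are 1 library each.

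Taking both ethanol groups against control, 29 of 32 unfolded protein genes, 15 of 17 glycolytic genes, 15 of 15 immediate early genes and 23 of 32 antioxidant genes lay below 0. Hsp90b1 was below the lowest control in 6 of 6 ethanol libraries (-2.12 ± 0.49 SE, adjusted p = 0.897). Pfkl, the liver form of phosphofructokinase, had 21.6 ± 13.8 CPM in controls, 2.07 ± 3.20 with 6% and 5.10 ± 2.80 with 10% ethanol (-2.71 ± 1.07, adjusted p = 0.999). Lcorl had 16.5 ± 13.7, 1.26 ± 0.586 and 1.28 ± 0.249 CPM (-3.70 ± 0.85, adjusted p = 0.897 by edgeR and 0.000320 by DESeq2). Higher in all 6 ethanol libraries than in any control were Zfp207, a spindle assembly protein, with 379 ± 61.6, 791 ± 209 and 729 ± 187 CPM (1.003 ± 0.36), Lrrc42, with 31.0 ± 4.53, 94.6 ± 38.4 and 89.3 ± 18.97 CPM (1.57 ± 0.48), and Ei24, a p53-induced gene, with 155 ± 48.4, 317 ± 95.5 and 309 ± 81.2 CPM (1.01 ± 0.40). The adjusted p of these 3 was 0.999.

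edgeR called 0 of 12488 genes for both ethanol groups against control, with 509 at an unadjusted p under 0.05, 139 higher and 370 lower. Without 6% ethanol 1, the only long-header library of the 6% group, there were 1266. DESeq2 called 38 and limma voom 0. The set test passed 5 of 29 lists. Unfolded protein (median -0.70, adjusted p = 9.56e-05, 0.550 with an estimated correlation), glycolysis (-0.82, 0.000145, 0.414), immediate early (-0.83, 0.00176, 0.590) and antioxidant genes (-0.39, 0.0117, 0.220) fell, and Y-linked genes rose (1.76, 0.00176, 0.220). In each bracket the last value is the adjusted p with an estimated correlation. The unfolded protein (median -0.29, adjusted p = 0.337) and immediate early (-0.47, 0.262) calls ended without control 1. Without control 2 the glycolysis (median -0.33, adjusted p = 0.0932), antioxidant (0.0980), immediate early (0.0980) and Y-linked (0.0521) calls ended. The medians of glycolysis and the immediate early list were -1.51 and -1.49 without 6% ethanol 1, and that of the unfolded protein list was -1.07 without control 3. Within header form the immediate early medians were -0.89 in long-header and -1.46 in short-header libraries, and the Y-linked ones 0.92 and 2.31. Control 2 was the only long-header control.

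In the fit to all 9 libraries no list of cell identity passed the set test. Of the pluripotency and inner cell mass list, 14 of 25 lay above 0 with both ethanol groups combined (adjusted p = 0.412), and of the trophectoderm list 8 of 24 (0.170). Krt8 and Krt18, the keratin pair of the trophectoderm, had 67.3 ± 41.6 and 255.7 ± 339 CPM in controls. Krt8 stood at 18.3 ± 13.2 CPM with 6% and 24.7 ± 18.4 with 10% ethanol, and Krt18 at 81.2 ± 16.5 and 49.4 ± 24.6. The control mean of Krt18 rested on control 2, at 647 CPM, and without that library the combined log2 fold change was 0.08. In the same combined comparison lists of 2-cell genes (adjusted p = 0.170), maternal oocyte transcripts (0.993), p53 targets (0.949), DNA damage response (0.993), imprinted genes (0.993) and DNA methylation and chromatin regulators (0.993) did not pass either. Alcohol, aldehyde and retinoid metabolism had 12 tested members and an adjusted p of 0.395.

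Within header form some of these lists passed. In long-header libraries the pluripotency list was higher at 10% ethanol than in control (median 0.70, adjusted p = 0.00197) and with both ethanol groups combined (0.44, 0.0155), whereas in short-header libraries its medians were -0.54 (0.104) and -0.49 (0.809). In short-header libraries the 2-cell list was higher at 10% ethanol than in control (median 3.28, adjusted p = 3.68e-15) and than at 6% ethanol (3.18, 1.41e-09), and with both ethanol groups combined (0.66, 0.00220). In long-header libraries these medians were -0.11 (0.600), 1.09 (0.188) and -0.11 (0.864). The p53 list was lower in short-header libraries at 10% ethanol than in control (-1.08, 0.0194), and stood at -0.18 (0.600) in long-header libraries. The long-header controls and the short-header 10% group are 1 library each, so these values may describe that library.

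Markers of other cells that an embryo pool could carry were read as list sums. In the fit to all 9 libraries these lists had too few tested members for the set test. The cumulus and granulosa list summed to between 15.9 and 228 CPM per library, the sperm and testis list to between 7.18 and 44.6 CPM, and the blood list to between 0.294 and 17.6 CPM. Sperm and testis sums were 37.4 ± 11.1 CPM in controls, 18.5 ± 9.97 with 6% and 15.8 ± 3.26 with 10% ethanol. Cumulus and granulosa sums were 148 ± 100, 86.7 ± 66.5 and 115 ± 19.3 CPM. Group differences in these sums were not tested.

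The sex mix of each library was read from Xist and the Y-linked genes. Eif2s3y, a Y-linked translation factor gene, had 7.12 ± 4.01 CPM in controls, 31.9 ± 16.3 with 6% and 19.1 ± 4.89 with 10% ethanol, and all 6 ethanol libraries lay above every control (1.79 ± 0.73 SE, adjusted p = 0.999). Uba1y had 0 counts in the 3 controls and 5.13 ± 6.39 and 5.71 ± 3.75 CPM in the ethanol groups, at least 84.4-fold more over both groups when 3 counts over all controls are taken as the limit. Uty had 6.61 ± 5.86 CPM in controls, 0.264 ± 0.457 with 6% and 4.73 ± 5.68 with 10% ethanol. Ddx3y had 26.2 ± 16.3, 62.7 ± 52.6 and 26.9 ± 4.86 CPM, with 123 CPM in 6% ethanol 2. Usp9y had 1.90 ± 0.215, 2.575 ± 2.18 and 11.6 ± 17.3 CPM, with 31.5 CPM in 10% ethanol 3. Xist, expressed from the inactive X chromosome of female cells, had 363 ± 219, 656 ± 685 and 164 ± 271 CPM. Per library it stood at 333, 161 and 596 CPM in controls, 14.1, 577 and 1377 with 6% ethanol, and 3.52, 11.4 and 476 with 10%. The 4 long-header libraries held the 4 lowest of these values.

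Log2 fold changes of 6% and of 10% ethanol against the same controls correlated at 0.408 across 12488 genes. In 100 simulated data sets with no effect the shared controls alone gave 0.474 to 0.520, with a mean of 0.498. The covariance was 0.758 against a simulated mean of 0.885. With header form as a term, in the data and in 100 simulations, the correlation was 0.53 against 0.451 to 0.504. Without control 1, 2 or 3 it was 0.535, 0.604 and 0.532, where simulations without the same control gave at least 0.606, 0.614 and 0.592. The observed value lay above the simulations only with header form as a term, and simulated genes varied independently of one another, so whether the doses are alike beyond their shared controls stays open.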

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

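The tests with header form, with each header form alone, with rRNA-like genes left out, with thinning, the list tests by library size alone, and the simulations of the correlation by header form and without a control were chosen only after the data were seen. The 4 counts of genes stayed at 0 with RLE scaling, library size alone, the stricter filter, the robust fit, limma voom, a surrogate variable, mitochondrial or rRNA-like genes left out, an adjusted p under 0.1, thinning, header form as a term and each left-out library. The fits of only the groups compared were made for the 3 pairs, where the counts were 0 as well. In what follows values are in the order 6% against control, 10% against control, 10% against 6%, and both against control. DESeq2 gave 53, 23, 63 and 38 genes. Nearly no filter gave 1, Mthfsd, for both against control. Long-header libraries alone gave 3, 9, 4 and 13 genes and 2, 3, 0 and 3 lists, and short-header libraries alone gave 48, 2, 1 and 5 genes and 4, 4, 3 and 4 lists. Of the DESeq2 calls 20, 14, 23 and 19 had a group with 0 counts throughout. In fits to one header form a group with 1 library is assumed to vary like the others. The spread came only from the 10% ethanol libraries in the long-header fit, and only from the control and 6% libraries in the short-header fit. These counts therefore rest on very few libraries and are no measure of what the fit to all 9 libraries missed. The cause of these differences was not tested. Without 6% ethanol 1 the genes at an unadjusted p under 0.05 numbered 2068, 442, 2208 and 1266 of 13631 tested. All 9 libraries gave 779, 267, 665 and 509 of 12488. That library was the only long-header one of its group, so the 6% group left behind was short-header alone. In comparisons that use the 6% group the rise therefore cannot be told apart from header form.

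The lists past the threshold, 6, 6, 2 and 5, went to 0 in each comparison with an estimated correlation and with fry's directional test. Fry's mixed test, which takes no account of direction, passed 2, 1, 0 and 1. These were the Y-linked list in each comparison with control and the antioxidant list at 6% against control. Library size alone gave 10 lists for 10% against control, and header form as a term gave 8 for both against control, and the cause was not tested. Over the left-out libraries the number of lists ranged from 4 to 9 for 6% against control, from 4 to 9 for 10% against control, from 1 to 4 for 10% against 6%, and from 1 to 9 for both against control. The correlation of the fold changes was 0.53 with header form as a term and ranged from 0.313 to 0.604 over the left-out libraries. Library size alone moved the median log2 fold change of all genes by -0.27, -0.12, 0.15 and -0.19, and under that scaling and RLE the median of every list that passed kept its sign.

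Of the 654, 592, 436 and 586 values of named genes under the alternatives other than thinning, rRNA-like genes left out, the threshold of 0.1 and fits to one header form, 644, 586, 425 and 575 kept their sign and stayed short of the threshold, and 7, 5, 9 and 8 passed it with the same sign. In long-header libraries alone the sign turned for Rpl31, Gdf3 and Rps10 at 6% against control, for Rpl31, Wwtr1, Dppa3, Fgf4 and Dppa4 at 10% against 6%, and for Gdf3 and Ndufb7 for both against control, and Eno1 and Krt18 passed at 10% and for both against control. In short-header libraries alone it turned for Eno1, Gabarapl1 and Utf1 at 10% against control. There Stk4, Mthfsd, Kmt2a and Dbr1 passed at 6% against control, Arl5c at 10%, and Mthfsd and Arl5c for both. With 1 surrogate variable the log2 fold change was -0.55 for Rpl31 and -1.29 for Rps10 at 6% against control, and 0.13 for Rpl31 and 0.20 for Dppa4 at 10% against 6%. Over the left-out libraries the log2 fold change of Rpl31, 6% vs control, ranged from -0.34 (without 6% ethanol 2) to 2.22, and the log2 fold change of Eno1, 10% vs control, from -3.14 to 0.61 (without control 2). The log2 fold change of Eno1, both ethanol groups vs control, ranged from -3.55 to 0.20 (without control 2), that of Krt18 from -2.53 to 0.077 (without control 2), and that of Rpl24 from -2.49 to 0.34 (without control 3). The cause was not tested. With median standard errors of 1.02, 1.01, 1.02 and 0.87 on the log2 scale, changes of 4-fold were recovered in 0 to 2 percent of simulated genes.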

Other observations

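The tests by header form, of developmental stage, of genes 100-fold above the other libraries, of genes moving together, of single libraries, of male embryos and of Uba1 reads were chosen only after the results were seen. Sequencing depth and the sex mix of the pools were also examined for the first pattern, and were dropped from the formal weighing after their values were known. The values are given here without a verdict. Thinned to equal depth, the median correlation was 0.888 among long-header and 0.780 among short-header libraries. The Y-linked log2 sum differed by -0.40, long minus short (exact permutation p = 0.452, 126 splits), and log2 Xist by -5.10 (exact p = 0.00794, 0.0238 adjusted over 3 measures).

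Between the 4 long-header and 5 short-header libraries, which cut across the sire groups, edgeR's quasi-likelihood test called 13 of 12488 genes, 5 higher and 8 lower in long-header libraries. Usp17lc, a gene of the 2-cell stage, was lower (log2 difference -9.74), as was Trim43b (-2.08), whereas Wnt3a (6.97), Ticam2 (8.75) and Psap (1.99), the precursor of the lysosomal saposins, were higher. Of the 2-cell and zygotic genome activation list 1 of 17 members lay above 0 (median -3.37, adjusted p = 4.47e-09). Trophectoderm genes lay above 0 in 20 of 24 (0.000601) and p53 targets in 27 of 30 (9.19e-05). Cytosolic ribosomal proteins lay above 0 in 10 of 79 (median -0.70, adjusted p = 4.80e-10) and mitochondrially encoded genes in 0 of 13 (-1.52, 1.32e-06). Nuclear encoded oxidative phosphorylation genes did so in 23 of 78 (-0.47, 0.00229). Compaction, glycolysis, chromatin, autophagy and histone lists also passed. The 10% group held more long-header libraries than either other group, so this difference alone would lower the ribosomal, mitochondrial and oxidative phosphorylation lists there. With an estimated correlation the smallest adjusted p over all lists was 0.230.

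The 4 long-header libraries were more alike than libraries of one group. A trend on transcript length and base composition was removed only from the difference between the header forms. Over the genes with both values the 2-cell median was -2.92 before and -2.47 after, so the difference of that list remained. Library correlations were not computed again after the removal, so whether such a trend made the long-header libraries alike stays open. Less starting RNA in the short-header libraries stays open: at equal depth 15416 ± 812 genes were detected in long-header and 14933 ± 942 in short-header libraries (exact permutation p = 0.429). Genes at least 100-fold above the median of the other libraries numbered 9.0 ± 3.56 in long-header and 26.2 ± 8.67 in short-header libraries (exact permutation p = 0.0159). These were counted in the full libraries, without thinning, so the lower depth of the short-header libraries may enter that difference. Embryos further on in development in the long-header libraries cannot be told apart from a library batch. The log2 ratio of trophectoderm to 2-cell sums was 1.45 in long-header and 0.25 in short-header libraries (exact permutation p = 0.0238, 0.0357 adjusted over 3 measures), but it restates the difference of these 2 lists given above. No biological explanation from the sire groups was tested.

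The unfolded protein, glycolysis and antioxidant lists were lower with paternal ethanol at a preset inter-gene correlation of 0.01. With an estimated correlation they did not pass (adjusted p = 0.550, 0.414 and 0.220). With header form as a term the largest adjusted p of the 3 in the set test was 0.00424 at the preset correlation. The medians of the 3 lists were higher in long-header libraries, by 0.53, 0.66 and 0.13. Long headers made up a larger share of the ethanol libraries than of the controls. An additive difference of that direction would raise these lists with ethanol, not lower them. The term was thus bound to deepen the drop, and the adjusted p with it adds no separate support. Within header form the medians were below 0 in long-header and short-header libraries, at -0.27 (adjusted p = 0.182) and -1.09 (0.00220) for the unfolded protein list, -0.80 (0.000992) and -0.74 (0.0695) for glycolysis, and -0.49 (0.182) and -0.38 (0.155) for the antioxidant list. The long-header control is 1 library, control 2, whose glycolysis sum was the highest of the 3 controls, so these values decide nothing alone. Genes of a list moving together between libraries may account for the unfolded protein and glycolysis calls, whose estimated correlations were 0.20 and 0.19. For the antioxidant list the estimated correlation was 0.0034, below the preset 0.01. The loss of that call is therefore not shown to come from genes moving together. Single libraries may do so in part, since 3 of 27 calls ended when a library was left out, the unfolded protein call without control 1 (0.337) and the glycolysis (0.0932) and antioxidant (0.0980) calls without control 2. An effect of the sire's treatment stays open.

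The Y-linked list was higher with paternal ethanol at the preset correlation (adjusted p = 0.00176). It did not pass with an estimated correlation (0.220), without control 2 (0.0521) or in long-header libraries alone (0.329). Reads of Uba1 counted for its Y-linked copy Uba1y at a steady ratio are argued against. The lowest ratio in an ethanol library predicts 43.9 Uba1y counts in the controls and 0 were seen, which was known when the test was chosen. The ratio was not steady, with 295 Uba1y and 8469 Uba1 counts in 6% ethanol 1 and 38 and 11269 in 10% ethanol 2. A ratio that varies by library was not tested. More male embryos in the ethanol pools cannot be told apart from other causes with these libraries, because Xist had a log2 fold change of 0.0198 ± 1.28 SE. Ddx3y (0.85 ± 0.69) and Eif2s3y (1.79 ± 0.73) lay above 0 and Uty below it (-2.39 ± 1.27). The Xist value pools header forms that differ. Among long-header libraries Xist stood at 161 CPM in the single control and at 3.52 to 14.1 CPM with ethanol. Among short-header libraries control and ethanol values overlapped. An effect of the sire's treatment also stays open.

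Other assignments of the libraries to groups were refitted. The real one is included in each tally. For both ethanol groups against control, 73 of 100 splits gave at least its 509 genes at an unadjusted p under 0.05 (highest other 3058) and 38 of 100 at least its 5 lists (13), so chance is not excluded. A real count of 0 genes is reached by every split, 100 of 100 here and 10 of 10 below, and decides nothing (highest other 219). For each pair of groups the 10 splits are too few for a share under 0.05. For 6% against control the real values were 0 genes, 779 genes at an unadjusted p under 0.05 and 6 lists, reached in 10, 4 and 3 splits, and the highest others were 1, 2640 and 8. For 10% against control they were 0, 267 and 6, reached in 10, 8 and 5 splits, with 0, 861 and 16 as the highest others. For 10% against 6% they were 0, 665 and 2, reached in 10, 3 and 10 splits, with 20, 2592 and 11. The split with 20 genes parted all 3 long-header from all 3 short-header libraries, and the one with 219 set control 3, 6% ethanol 2 and 6% ethanol 3, all short-header, against the rest, which points to a structure of the libraries. With header form as a term the real groups gave 0 genes in each comparison and 989, 354, 491 and 736 at an unadjusted p under 0.05.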
